A study of Mus musculus with 12 samples.

How the data were processed

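Liver RNA of wild-type C57BL/6J mice was sequenced in 12 libraries, 3 in each of 4 groups: a diet named CD, which the labels do not spell out, a high-fat diet (HFD), and both with 2% dextran sulfate sodium (DSS). The route and duration of DSS, the sex of the mice and whether the libraries of a group came from separate mice are not given in the sources used here. Total RNA was extracted with a Qiagen RNeasy kit and libraries were made with a SMARTer mRNA-seq kit, per the labels' protocols. The groups and replicate numbers were taken from the sample labels. The mouse genome build was mm10, per the submitters' processing notes, and the aligner, counter and their versions are not given in the sources used here.

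The values used were FPKM per gene as deposited by the authors, fragment numbers normalised to gene length and to the fragments of the library, with 1 column per library and no pooling. The table held 54532 gene IDs, of which 54409 (99.8%) had a symbol and an exon length in the mm10 GENCODE annotation of the mouse genome, and 25911 were above 0 in at least 1 library. It also held 4 columns with no name and no value, which were not used. Multiplied by the summed exon length of the gene, 97.0 to 97.3% of the values under 500 fragments per library lay within 0.02 of a whole number of fragments. The recovered fragments, summed over the genes, gave the depth of each library: 24.4, 24.8 and 26.9 M fragments in CD 1 to 3, 25.7, 24.4 and 23.9 in HFD 1 to 3, 29.4, 25.2 and 25.5 in CD_DSS 1 to 3, and 23.4, 26.5 and 24.6 in HFD_DSS 1 to 3. The total by which the authors divided their FPKM, read from the size of the steps, was 0.927 to 1.05 times that sum. After this ratio and a trimmed mean of M-values factor were each centred on their geometric mean over the libraries, they lay within 0.00891 of each other on the log2 scale, so the deposited values carry a scaling between libraries beyond depth.

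Values were analysed as log2(FPKM + 1), so that fold changes of genes near or under 1 FPKM are understated, and folds in the text are of FPKM + 1. The 10806 genes with at least 1 FPKM in at least 3 of the 12 libraries were tested. One linear model with the 4 group means was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a variance trend, two-sided tests), and p-values were adjusted over the genes tested by the Benjamini-Hochberg method with a threshold of 0.05. The 5 comparisons were HFD against CD, CD_DSS against CD, HFD_DSS against HFD, HFD_DSS against CD_DSS, and the difference between both DSS effects. Of 39 gene lists of liver pathways, stress responses and cell type markers, 35 had at least 5 tested members and were tested with limma's camera at its preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it, and adjustment was over the lists of a comparison. No list test held with an estimated correlation in any comparison (0 lists).

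The test, the comparisons, the gene lists, the alternatives listed as planned and the rule for named genes were chosen before the data were examined. By that rule the text names, per comparison, up to 10 genes with the highest and 10 with the lowest log2 fold change among those called whose groups did not overlap (this condition was not applied to the difference between DSS effects), with a mean of at least 1 FPKM and a symbol that is not a clone or prediction name. It adds up to 6 called members of each list called by camera, and 25 genes fixed in advance with their values whatever the test gave. Outside the rule and chosen after their values were seen are called members of lists that camera did not call in that comparison, in the report and the closing section, and genes of the closing section's own tests, such as Clec4g, Atg7, Sox9, Cry1, C3 and Oat. The same holds for values of a named gene in a comparison in which the rule did not take it. Values of a few genes that the rule takes are not reported here.

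Before use, the tests were run on simulated data drawn from the real means and spread. For DSS on the CD diet (10601 genes), 44%, 66%, 86% and 94% of 50 genes each were called at simulated changes of 1.5, 2, 4 and 8-fold, with 9 false among 170 calls. Limma's camera gave 5.93e-40 for a list of 30 genes changed 1.5-fold and 0.112 for a list of 30 unchanged genes. The simulated data were drawn from means and spread, not from the correlation between genes. They therefore do not test how camera at its preset correlation performs on lists of correlated genes. For HFD against CD with no simulated change, 0 genes were called.

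Alternatives planned in advance were a pseudocount of 0.1, no filter on low values, a filter at a mean of 5 FPKM, TPM, median-of-ratios and quantile scaling, a fit of the 2 groups alone, library weights, a robust variance prior, the replicate number as a block, a minimum absolute log2 fold change of 1, and leaving out each library in turn. After the data were seen, voom on the recovered fragments was added, and a fit without HFD 1, CD_DSS 1 and HFD_DSS 2. Gene positions and exon overlaps were taken from the mm10 annotation, since fragments of overlapping genes and of near-identical family members could have been divided between them in ways that the sources used here do not give.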

Results

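RNA sequencing measured gene expression in the liver of wild-type C57BL/6J mice, an inbred laboratory strain. The mice were on a diet named CD or on a high-fat diet (HFD), each without and with 2% dextran sulfate sodium (DSS), a sulfated polysaccharide that injures the colon and is used to induce colitis in mice. The 12 libraries formed 4 groups of 3, named CD, HFD, CD_DSS and HFD_DSS. Expression was given as FPKM. Depth was 23.4 (HFD_DSS 1) to 29.4 M fragments (CD_DSS 1). In all, 10806 genes were tested. The labels do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The series title names autophagy and liver-gut crosstalk as its subject, and the comparisons asked what DSS changed on each diet, what the diet changed with and without DSS, and whether the DSS effect differed between the diets.

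On the first principal component (43.3% of the variance of the tested genes), all but 3 libraries separated by DSS. The 5 other untreated libraries lay from −21.7 to −19.1 and the 4 other DSS libraries from 21.7 to 30.9. Between them lay HFD 1 (−2.90), HFD_DSS 2 (7.64) and CD_DSS 1 (−4.75), the latter below untreated HFD 1. The second component held 15.6% and placed HFD 1 at −21.7 and CD_DSS 1 at 20.3. Saa1, which encodes the acute phase protein serum amyloid A1, had 579 FPKM in HFD 1 against 19.9 and 22.4 in HFD 2 and 3. In CD_DSS 1 it had 9.14 against 595 and 483 in CD_DSS 2 and 3, and in HFD_DSS 2 it had 191 against 1104 and 2670 in HFD_DSS 1 and 3. These libraries were kept in every comparison and left out in turn. The correlation of log2 values between libraries was 0.972 to 0.989 within groups and 0.949 to 0.988 between groups, and no 2 libraries agreed within sampling noise.

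**Figure D1:**
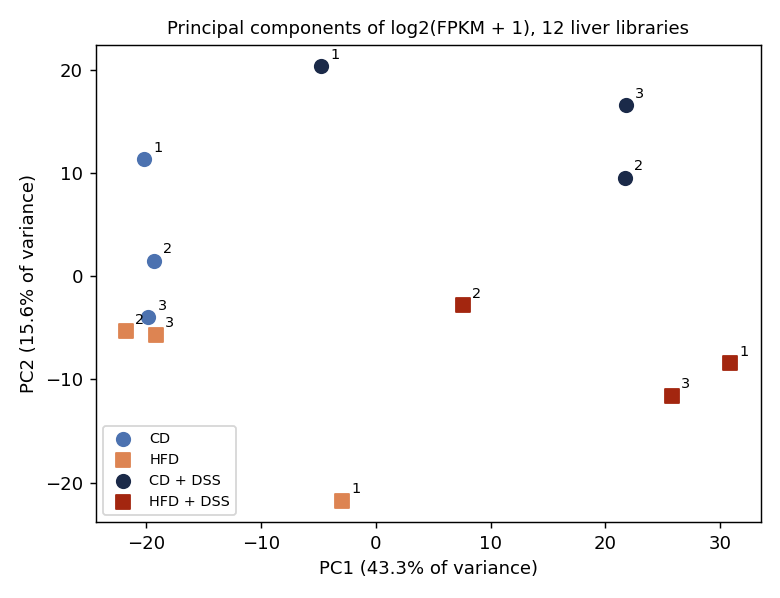
First 2 principal components of log2(FPKM + 1) over the 10806 tested genes, 1 point per library, with the share of variance on each axis and colours for the 4 groups. HFD 1 (−2.90), CD_DSS 1 (−4.75) and HFD_DSS 2 (7.64) lie between the other untreated libraries and the other DSS libraries on the first component.

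On the CD diet, DSS lowered Glul, which encodes glutamine synthetase, from 259.7 ± 30.3 FPKM (SD, n = 3) to 27.2 ± 10.8 (SD, n = 3), a 9.67-fold decrease of FPKM + 1 (limma adjusted p = 0.00272). Cyp8b1, the sterol 12α-hydroxylase of bile acid synthesis, fell 2.78-fold, from 294 ± 42.3 to 105.1 ± 16.5 FPKM (SD, n = 3; limma adjusted p = 0.00300). Thrsp, a lipogenic regulator, fell 7.30-fold, from 104 ± 34.6 to 13.3 ± 4.46 FPKM (limma adjusted p = 0.00272). Zbtb16, a zinc finger transcription factor, rose 2.96-fold, from 3.11 ± 0.894 to 11.0 ± 1.44 FPKM (SD, n = 3; limma adjusted p = 0.00258). Socs3, a feedback inhibitor of cytokine signalling, rose 4.95-fold, from 1.18 ± 0.230 to 9.88 ± 1.91 FPKM (limma adjusted p = 0.00772). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 32.5 ± 15.7 to 1.30 ± 1.00 FPKM (log2 fold change −3.83, SE 0.68, limma adjusted p = 0.0159).

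Other large increases on the CD diet were those of the neutrophil chemoattractant Cxcl1 (log2 fold change 3.29, SE 0.65), the co-chaperone gene Dnajc12 (2.90), the acyltransferase gene Acnat2 (2.35) and Tacc2 (1.86). Smaller ones were those of the secreted lipid regulator Angptl8 (1.57), the receptor ligand Gas6 (1.56), Junb (1.45) and the transcription factor Klf10 (1.40). Large decreases were those of Nat8f5 (−3.08, SE 0.63), the carboxylesterase Ces2c (−2.85), the pseudogene Serpina4-ps1 (−2.64), G6pc, the glucose-6-phosphatase of glucose output (−2.42), Cyp4a12a (−2.27) and the succinate receptor Sucnr1 (−2.21). Mup-ps20, a pseudogene of the major urinary protein family, averaged 5.16 ± 3.85 FPKM in CD (SD, n = 3) and was listed at 0 in all 3 CD_DSS libraries. Members of the Mup, Ces2, Ugt2b, Cyp4a and Nat8f families have near-identical copies, and the counting method is not given in the sources used here, so their values are uncertain. Nat8f5 shares 13.7% of its exon bases with Nat8f6, and Junb shares 7.52% with Prdx2 on the opposite strand.

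In mm10 coordinates, Glul (ENSMUSG00000026473) lies on chromosome 1 from 153899944 to 153909723, Cyp8b1 (ENSMUSG00000050445) on chromosome 9 from 121914356 to 121916305, and Cyp7a1 (ENSMUSG00000028240) on chromosome 4 from 6265612 to 6275633. Thrsp (ENSMUSG00000035686) lies on chromosome 7 from 97412938 to 97417730, Socs3 (ENSMUSG00000053113) on chromosome 11 from 117966079 to 117970047, Cxcl1 (ENSMUSG00000029380) on chromosome 5 from 90891241 to 90893115, and Zbtb16 (ENSMUSG00000066687) on chromosome 9 from 48654297 to 48836222. All of these are annotated as protein-coding genes, and values refer to their summed exons.

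Metabolic gene lists were lower with DSS on the CD diet. Of 13 bile acid synthesis genes, 4 fell (Cyp7a1, Cyp8b1, Akr1d1 −0.94 and Acox2 −0.52) and 9 were not called, 7 fell adjusted over the list alone, and the camera adjusted p was 8.18e-07 (adjusted p = 0.133 with an estimated correlation). Of 21 genes of fatty acid and triglyceride synthesis, 5 fell (Thrsp, Acacb −1.59, Acss2 −1.5, Acly −1.07, Agpat2 −0.48), and 11 did so adjusted over the list alone (camera adjusted p = 2.64e-07; adjusted p = 0.417 with an estimated correlation). Of 24 cholesterol synthesis genes, 4 fell (Insig1 −0.70, Dhcr7 −0.69 and Stard4 −0.59 among them). Adjusted over the list alone, 5 fell and 1 rose (camera adjusted p = 1.19e-05; adjusted p = 0.442 with an estimated correlation). Of 28 genes of the urea cycle and amino acid catabolism, 11 fell (Glul, Prodh −1.02 and Got1 −0.96 among them), and 15 did so adjusted over the list alone (camera adjusted p = 4.45e-08; adjusted p = 0.269 with an estimated correlation). Of 21 genes of gluconeogenesis and glycolysis, G6pc and Tat (−1.23) fell, and 3 did so adjusted over the list alone (camera adjusted p = 7.12e-04; adjusted p = 0.269 with an estimated correlation). CD_DSS 1 stood apart from CD_DSS 2 and 3 in some of these lists, given as medians per library against the mean over libraries. For fatty acid and triglyceride synthesis it had 0.25 against −0.38 and −0.30, with 0.46 to 0.63 in CD, and for bile acid synthesis −0.07 against −0.38 and −0.47, with 0.18 to 0.29 in CD. For gluconeogenesis and glycolysis it had 0.08 against −0.09 and −0.12, with 0.12 to 0.31 in CD.

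Genes with higher expression in male than in female mouse liver were lower too: 10 of 19 fell, 15 adjusted over the list alone, with a median log2 fold change of −1.29 (camera adjusted p = 6.94e-11; adjusted p = 0.191 with an estimated correlation). Examples were Hsd3b5 (−1.90), Selenbp2 (−1.82) and Nudt7 (−1.64). None of 33 nuclear genes of oxidative phosphorylation was called by limma, against 14 that fell adjusted over the list alone, and all 33 had a negative log2 fold change (median −0.28, camera adjusted p = 4.12e-09; adjusted p = 0.417 with an estimated correlation). The median per library of this list was −0.01 in CD_DSS 1, −0.10 and −0.20 in CD_DSS 2 and 3, and 0.01 to 0.26 in CD. Of 13 mitochondrially encoded genes, mt-Co1 (−0.54) and mt-Nd3 (−0.48) fell, 3 adjusted over the list alone, with a median of −0.37 (camera adjusted p = 0.00127; adjusted p = 0.269 with an estimated correlation).

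Inflammatory gene lists were higher. Of 32 acute phase genes, 3 rose (Socs3, Fga 1.24, Stat3 0.85) and 29 were not called. Adjusted over the list alone, 19 rose and 1 fell, and the median log2 fold change was 1.25 (camera adjusted p = 6.94e-11; adjusted p = 0.442 with an estimated correlation). CD_DSS 1 had an acute phase median of −0.67 against the mean over libraries, beside 0.92 and 1.03 in CD_DSS 2 and 3 and −0.88 to −0.67 in CD. The serum amyloid genes Saa1 (2.25, SE 1.65) and Saa2 (3.02, SE 1.89), Lcn2 (3.39, SE 1.46) and the hepcidin gene Hamp (−2.75, SE 1.08) did not pass (limma adjusted p = 0.448, 0.371, 0.194 and 0.158). Cxcl1 was the 1 called gene of 16 inflammatory cytokines and NF-kB targets, 5 of which rose adjusted over the list alone (camera adjusted p = 0.00147; adjusted p = 0.448 with an estimated correlation). This list had a median per library of −0.08 in CD_DSS 1 against 0.28 and 0.40 in CD_DSS 2 and 3. The call of Cxcl1 ended without any 1 library of the comparison but CD_DSS 1 (limma adjusted p from 0.0546 to 0.0871), and Il1b had 0.17 (SE 0.33). Ccl2 and Tnf stayed under the expression filter. Of 34 interferon-stimulated genes, 3 rose (Igtp 0.83, which shares 8.01% of its exon bases with Irgm2, Gbp3 0.55 and Irf9 0.51), and 12 did so adjusted over the list alone (camera adjusted p = 4.89e-06; adjusted p = 0.503 with an estimated correlation).

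Macrophage and Kupffer cell markers moved with these lists on the CD diet: 1 of 16 rose (Cd9 0.87), 10 adjusted over the list alone, with a median of 0.60 (camera adjusted p = 5.27e-07; adjusted p = 0.417 with an estimated correlation). The macrophage median per library was −0.24 in CD_DSS 1, within the −0.44 to −0.16 of CD, against 0.46 and 0.56 in CD_DSS 2 and 3. Adgre1 had 0.56 (SE 0.24, limma adjusted p = 0.192). None of 7 neutrophil markers was called (median 0.67, camera adjusted p = 0.0195; adjusted p = 0.583 with an estimated correlation). The list call ended without CD 3 (0.0504) and without CD_DSS 2 (0.0721), and CD_DSS 1 (−0.70) lay within the range of CD (−0.86 to −0.53), against 0.67 and 0.43 in CD_DSS 2 and 3. Of 14 endothelial markers, Clec4g, named after its value was seen, rose (0.48) and the median was 0.01 (camera adjusted p = 0.614). Immediate early genes were higher, with 4 of 15 called and the same number adjusted over the list alone (Junb, Ier3 0.89, Atf3 0.72, Gadd45b 0.72; camera adjusted p = 0.00109; adjusted p = 0.269 with an estimated correlation; 0.0758 at a mean of at least 5 FPKM). Of 17 ATF4 targets of the integrated stress response, 3 rose (Ddit3 1.31, Atf3, Atf5 0.47), and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.0464; adjusted p = 0.417 with an estimated correlation). That list call ended without CD 1 (0.0750), CD_DSS 1 (0.196) or the 3 intermediate libraries (0.258), with median-of-ratios scaling (0.0543), with libraries weighted (0.121) and at a mean of at least 5 FPKM (0.265). Of 23 genes of the unfolded protein response none was called, over all genes or adjusted over the list alone (median 0.39, camera adjusted p = 9.73e-04; adjusted p = 0.643 with an estimated correlation). The list call ended without CD 1 (0.0977), which had a median of −0.69 against −0.02 and −0.07 in CD 2 and 3. CD_DSS 1 had −0.16, below CD 2 and CD 3, against 0.14 and 0.21 in CD_DSS 2 and 3.

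On the CD diet, limma called 519 genes, 217 higher and 302 lower (41.8% higher), at a Benjamini-Hochberg adjusted p under 0.05, and TPM scaling called 384, 239 higher and 145 lower (62.2% higher). All 519 had the 3 libraries of one group above all 3 of the other, as did 27.0% of the tested genes, where chance gives 10%. The count was 212, 79 and 141 without CD 1, 2 and 3, 1271 without CD_DSS 1, 84 and 63 without CD_DSS 2 and 3, and 1924 without the 3 intermediate libraries. It was 2592 with libraries weighted, 220 from a fit of these 2 groups alone and 157 with no filter on low values. Medians per library overlapped between CD and CD_DSS in 5 of the 19 called lists (lysosome, unfolded protein response, heat shock, macrophage and neutrophil markers). Of the 55 genes that the naming rule took as called, 19, 11 and 13 kept the call without CD 1, 2 and 3, 55 without CD_DSS 1, and 9 and 10 without CD_DSS 2 and 3. Those that kept it without any 1 library were Cd9, Cyp8b1, Glul, Klf10, Selenbp2, Serpina4-ps1, Socs3, Thrsp and Zbtb16. Cyp7a1 lost it without CD 3, CD_DSS 2 or CD_DSS 3 (adjusted p = 0.0590, 0.0636 and 0.0698).

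**Figure D2:**
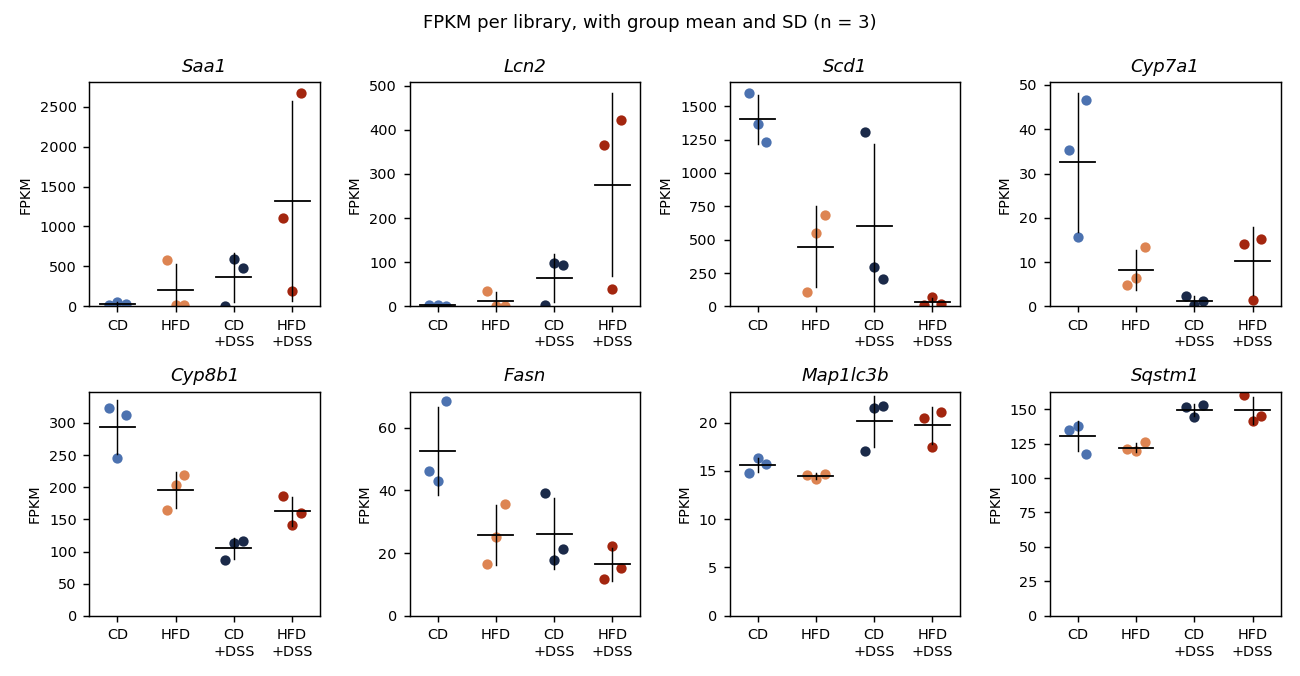
FPKM of Saa1, Lcn2, Scd1, Cyp7a1, Cyp8b1, Fasn, Map1lc3b and Sqstm1 in each of the 12 libraries, by group, with the group mean and SD (n = 3). Cyp8b1 averages 294 FPKM in CD and 105.1 in CD_DSS, and Saa1 is at 9.14 FPKM in CD_DSS 1 against 595 and 483 in the other CD_DSS libraries.

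On the high-fat diet, DSS raised Zbtb16 4.55-fold, from 1.61 ± 0.297 to 10.9 ± 1.5 FPKM (SD, n = 3; limma adjusted p = 2.39e-04). Cyp2a5, a cytochrome P450 of the coumarin 7-hydroxylase type, fell 14.7-fold, from 43.8 ± 8.05 to 2.14 ± 1.11 FPKM (SD, n = 3; limma adjusted p = 0.00263). Gls2, the liver glutaminase, fell 2.08-fold, from 90.1 ± 23.9 to 41.8 ± 0.489 FPKM (limma adjusted p = 0.0110). Scd1, the stearoyl-CoA desaturase, fell from 447 ± 302 to 31.3 ± 34.7 FPKM (log2 fold change −3.99, SE 0.88, limma adjusted p = 0.0326). Glul fell 5.32-fold, from 259.9 ± 21.4 to 53.7 ± 33.3 FPKM, and Socs3 rose 5.36-fold, from 2.43 ± 1.5 to 17.4 ± 8.34 FPKM (limma adjusted p = 0.0110 and 0.00978). Cyp2a5 (ENSMUSG00000005547) lies on chromosome 7 from 26835305 to 26843548 and Scd1 (ENSMUSG00000037071) on chromosome 19 from 44394455 to 44407879 (mm10), both protein-coding.

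Other large increases on the high-fat diet were those of the metallothionein Mt2 (log2 fold change 4.84, SE 1.22), Cxcl1 (3.68), the pentraxin Apcs (3.19), Isyna1 (2.74), Dnajc12 (2.65), Fgl1 (2.42), Cxcl14 (1.99) and the scavenger receptor Marco (1.90). Of the exon bases of Mt2, 73.5% overlap the antisense gene Gm45774, so its value is uncertain. Large decreases were those of Ces2c (−3.55, SE 0.56), Mup-ps20 (−2.55), Hamp2 (−2.48), Cyp4a12b (−2.46), Sucnr1 (−2.40), the carbonic anhydrase Car3 (−2.30) and G6pc (−2.23).

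Lists of acute phase and protein folding genes were higher on the high-fat diet. Of 32 acute phase genes, 7 rose (Mt2, Apcs, Socs3, Itih4 1.48, Fga 1.28, Cp 0.94 and Stat3 0.60) and 25 were not called. The counts were 24 higher and 1 lower adjusted over the list alone (median 1.51, camera adjusted p = 1.98e-14; adjusted p = 0.421 with an estimated correlation). Per library, the acute phase median was 0.21 in HFD 1 against −0.92 and −0.91 in HFD 2 and 3, and 0.21 in HFD_DSS 2 against 1.29 and 1.42 in HFD_DSS 1 and 3. Saa1 (3.65, SE 1.65), Saa2 (4.55, SE 1.89), Lcn2 (5.14, SE 1.46) and Hamp (−2.70, SE 1.08) were not called (limma adjusted p = 0.208, 0.174, 0.0669 and 0.161). Of 23 genes of the unfolded protein response, 4 rose (Pdia4 1.19, Hsp90b1 1.16, Dnajc3 0.79, Canx 0.36), and 21 did so adjusted over the list alone (median 0.79, camera adjusted p = 1.30e-11; adjusted p = 0.401 with an estimated correlation). The median per library of this list was 0.02 in HFD_DSS 2 against 0.74 and 0.61 in HFD_DSS 1 and 3, and −0.02 in HFD 1 against −0.47 and −0.33 in HFD 2 and 3. Of 17 ATF4 targets, Asns (1.42), Ddit3 (1.14) and Atf3 (0.74) rose. Adjusted over the list alone, 6 rose and 1 fell (camera adjusted p = 0.00146; adjusted p = 0.258 with an estimated correlation). Immediate early genes had 4 of 15 called higher, 7 adjusted over the list alone (Junb 1.64, Gadd45b 1.01, Klf6 0.50; camera adjusted p = 3.17e-04; adjusted p = 0.258 with an estimated correlation). At a mean of at least 5 FPKM the calls of both lists ended (0.0754 for ATF4 targets and 0.0708 for immediate early genes).

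Of 16 inflammatory cytokines and NF-kB targets, Cxcl1 and Nfkbiz (1.87) rose and Il18 (−0.36) fell. The counts were 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0158; adjusted p = 0.524 with an estimated correlation). The list call ended without HFD 3 (0.0996) and without HFD_DSS 3 (0.0699), and its median per library was higher in HFD 1 (0.23) than in HFD_DSS 2 (−0.07). Il1b had −0.08 (SE 0.33). Macrophage markers moved with these lists: Marco and Cd9 (0.49) rose among 16, and the same number adjusted over the list alone (median 0.48, camera adjusted p = 1.39e-05; adjusted p = 0.421 with an estimated correlation), with Adgre1 at 0.58 (SE 0.24). Their median per library was 0.16 in HFD 1 against −0.31 and −0.41 in HFD 2 and 3, and 0.0026 in HFD_DSS 2 against 0.32 and 0.41 in HFD_DSS 1 and 3. The 7 neutrophil markers had a median of 1.22 with none called and 1 higher adjusted over the list alone (camera adjusted p = 0.00382; adjusted p = 0.421 with an estimated correlation). Here too HFD 1 (0.44) lay above HFD_DSS 2 (−0.19). The 14 endothelial markers had a median of −0.07 (camera adjusted p = 0.771). Of 34 interferon-stimulated genes none was called (median 0.14, camera adjusted p = 0.0146; adjusted p = 0.635 with an estimated correlation), a list call that ended without HFD 2 (0.0891), HFD 3 (0.203) and HFD_DSS 1 (0.190) and at a mean of at least 5 FPKM (0.0977). HFD 1 (0.33) lay above HFD_DSS 2 and 3 (0.10 and 0.11) in this list.

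Several metabolic lists were lower on the high-fat diet. Of 33 nuclear oxidative phosphorylation genes, 8 fell (Sdhb −0.57, Cyc1 −0.51, Atp5c1 −0.49 and Uqcrc1 −0.49 among them), and 25 did so adjusted over the list alone (median −0.39, camera adjusted p = 1.98e-14; adjusted p = 0.329 with an estimated correlation). The 13 mitochondrially encoded genes had a median of −0.24 with mt-Co1 (−0.60) lower (camera adjusted p = 0.0536). Of 28 genes of the urea cycle and amino acid catabolism, 8 fell (Glul, Hal −1.20, Gls2 −1.06, Ass1 −0.85 among them), and 17 did so adjusted over the list alone (camera adjusted p = 6.10e-09; adjusted p = 0.258 with an estimated correlation). Of 21 genes of fatty acid and triglyceride synthesis, Scd1, Thrsp (−2.05) and Acly (−0.70) fell, and 8 did so adjusted over the list alone (camera adjusted p = 8.50e-06; adjusted p = 0.421 with an estimated correlation). HFD_DSS 2 (−0.08) lay above HFD 1 (−0.15) in this list, with −0.77 and −0.73 in HFD_DSS 1 and 3 and 0.10 and 0.22 in HFD 2 and 3. Of 19 male-high genes, 5 fell (Cyp4a12b, Cyp4a12a −1.95, Ugt2b38 −1.56, Ugt2b1 −1.53, Mup20 −1.02), and 11 did so adjusted over the list alone (median −0.86, camera adjusted p = 6.79e-07; adjusted p = 0.259 with an estimated correlation). Of 21 genes of gluconeogenesis and glycolysis, 4 fell (G6pc, Pygl −0.85, Eno1 −0.60, Pgam1 −0.38), and 6 did so adjusted over the list alone (camera adjusted p = 0.00382; adjusted p = 0.396 with an estimated correlation).

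Genes of drug and toxin metabolism were lower with DSS on the high-fat diet: of 21 targets of the receptors CAR, PXR and AHR, 6 fell (Cyp2a5, Cyp1a2 −2.22, Cyp3a11 −1.62 and Cyp2c29 −1.14 among them) and Por rose (1.03). Adjusted over the list alone, 7 fell and 3 rose (camera adjusted p = 0.0158; adjusted p = 0.492 with an estimated correlation). Of 25 glutathione and NRF2 genes, Gsta4 (−1.38), Gsta3 (−1.22) and Gstp1 (−0.77) fell, and 11 did so adjusted over the list alone (camera adjusted p = 5.49e-04; adjusted p = 0.421 with an estimated correlation). Bile acid synthesis had 1 of 13 genes called lower, Amacr (−0.65), and 3 fell adjusted over the list alone (camera adjusted p = 0.00116; adjusted p = 0.258 with an estimated correlation). Cholesterol synthesis genes had a positive median on the high-fat diet, and 3 of 24 rose (Sqle 1.23 and Fdps 0.92 among them), 9 adjusted over the list alone (median 0.46, camera adjusted p = 6.26e-05; adjusted p = 0.421 with an estimated correlation). The groups overlapped in the median per library of this list, which was 0.36, 0.28 and −0.06 in HFD_DSS 1 to 3 and −0.30, −0.47 and 0.03 in HFD 1 to 3. Sqle lost its call without HFD 2, HFD_DSS 1 or HFD_DSS 3 (limma adjusted p = 0.0692, 0.0861 and 0.0539). The list call ended without the 3 intermediate libraries (median 0.37, adjusted p = 0.0933), and 26.7% of the exon bases of Fdps are shared with Gm43738.

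On the high-fat diet, limma called 522 genes, 187 higher and 335 lower (35.8% higher), and TPM scaling called 367, 245 higher and 122 lower (66.8% higher). In 521 of the 522 the groups did not overlap, as in 27.1% of the tested genes, where chance gives 10%. The count was 742, 9 and 117 without HFD 1, 2 and 3, 35, 879 and 37 without HFD_DSS 1, 2 and 3, and 2027 without the 3 intermediate libraries. It was 2820 with libraries weighted, 122 from a fit of these 2 groups alone and 130 with no filter on low values. Medians per library overlapped between HFD and HFD_DSS in 9 of the 19 called lists (cholesterol synthesis, fatty acid and triglyceride synthesis, acute phase, inflammatory, interferon-stimulated, fibrosis, macrophage, neutrophil and erythroid). Of 72 genes that the naming rule took as called, 60, 3 and 18 kept the call without HFD 1, 2 and 3, and 7, 67 and 9 without HFD_DSS 1, 2 and 3. Cyp2a5, Gls2 and Zbtb16 kept it without any 1 library, and Glul and Socs3 lost it without HFD 2 alone (adjusted p = 0.0626 and 0.0566). Scd1 lost it without HFD 2, HFD 3, HFD_DSS 1 or HFD_DSS 3 (adjusted p = 0.144, 0.0955, 0.129 and 0.111).

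With DSS, autophagy genes were called about as often as tested genes in general. Of all 10806, limma called 519 with DSS on the CD diet and 522 on the high-fat diet. None of the 33 core machinery genes or 12 receptors was called between the diets, without or with DSS. The 2 lists were called by camera in none of the 5 comparisons (adjusted p between 0.385 and 0.952 for the core list and between 0.270 and 0.825 for the receptors). The receptor gene Sqstm1 (p62) had log2 fold changes of 0.20 (SE 0.09) with DSS on the CD diet and 0.28 (SE 0.09) on the high-fat diet (limma adjusted p = 0.214 and 0.0944), −0.09 between the diets without DSS and −0.01 with DSS. Map1lc3b (LC3B) had 0.34 on the CD diet (SE 0.10, limma adjusted p = 0.0854). It rose on the high-fat diet from 14.5 ± 0.291 to 19.7 ± 1.93 FPKM (SD, n = 3; 0.41, limma adjusted p = 0.0458). This call ended without HFD 1 (0.0612), HFD 2 (0.169), HFD 3 (0.0996), HFD_DSS 1 (0.163) or HFD_DSS 3 (0.161). For Map1lc3b the difference between these DSS effects was 0.08 (SE 0.15, limma adjusted p = 1.00). Ulk1 had 0.57 and 0.31 with DSS on the CD and the high-fat diet, Becn1 0.15 and 0.06, and Tfeb 0.25 and 0.06, none of them called. Between the diets without and with DSS, Map1lc3b had −0.10 and −0.02, Ulk1 −0.10 and −0.36, and Becn1 0.08 and −0.02, none called. With values adjusted over the list alone, 4 core genes rose and 1 fell with DSS on the CD diet, and 2 rose and 2 fell on the high-fat diet. Of the receptors, 1 was higher and 1 lower with DSS on the CD diet, 0 on the high-fat diet, and 1 was higher and 2 lower between the diets with DSS, adjusted over the list alone. Chosen after their values were seen, the called autophagy genes outside the naming rule were Atg7 (−0.35) and Optn (−0.40) with DSS on the CD diet, and Atg101 (−0.60) and Atg14 (0.39) with DSS on the high-fat diet. Sqstm1 (ENSMUSG00000015837, chromosome 11 from 50199366 to 50210827 in mm10) shares 17.3% of its exon bases with Mrnip on the opposite strand, and Becn1 43.9% with Cntd1. The 39 lysosomal genes had medians of 0.06 with DSS on both diets (camera adjusted p = 0.0464 and 0.122; adjusted p = 0.643 and 0.626 with an estimated correlation). The call on the CD diet ended without CD 1, CD 2, CD_DSS 2 or CD_DSS 3 (0.0615, 0.124, 0.0569 and 0.439).

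Among the genes fixed in advance whose values were not given above, none was called with DSS on either diet. On the CD and the high-fat diet respectively, the log2 fold changes were −0.47 and −0.68 for the bile salt export pump Abcb11, −0.05 and 0.01 for the nuclear receptor Nr0b2, −1.03 and −0.59 for Fasn, and −0.63 and −0.98 for Srebf1. They were −0.18 and −0.27 for Cd36, −0.55 and 0.15 for Pparg, 0.81 and 0.88 for Fgf21, and 0.06 and 0.06 for Cidec. Between the diets with DSS they were −0.38 (Abcb11), −0.40 (Nr0b2), −0.60 (Fasn), −0.30 (Srebf1), −0.12 (Cd36), 0.24 (Pparg), 0.41 (Fgf21), 0.18 (Cidec), 2.53 (Saa1), 2.80 (Saa2), 2.53 (Lcn2), 0.32 (Hamp), −0.02 (Adgre1), 0.63 (Cyp8b1) and 1.97 (Cyp7a1), none called. Without DSS they were −0.46 for Pparg, 0.34 for Fgf21, 0.18 for Cidec, 0.46 for Il1b and 0.01 for Tfeb.

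The DSS effects on the 2 diets, which share no library, correlated across the 10806 genes with Pearson r = 0.716 and Spearman rho = 0.646; genes are not independent replicates. The Pearson r lay between 0.658 and 0.733 when single libraries were left out. Both comparisons called 72 genes higher (3.76 expected for independent lists) and 116 lower (9.36 expected), and 0 in opposite directions. Of the 519 genes called on the CD diet, 496 had the same sign on the high-fat diet, and of the 522 called there, 502 had the same sign on the CD diet.

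**Figure D3:**
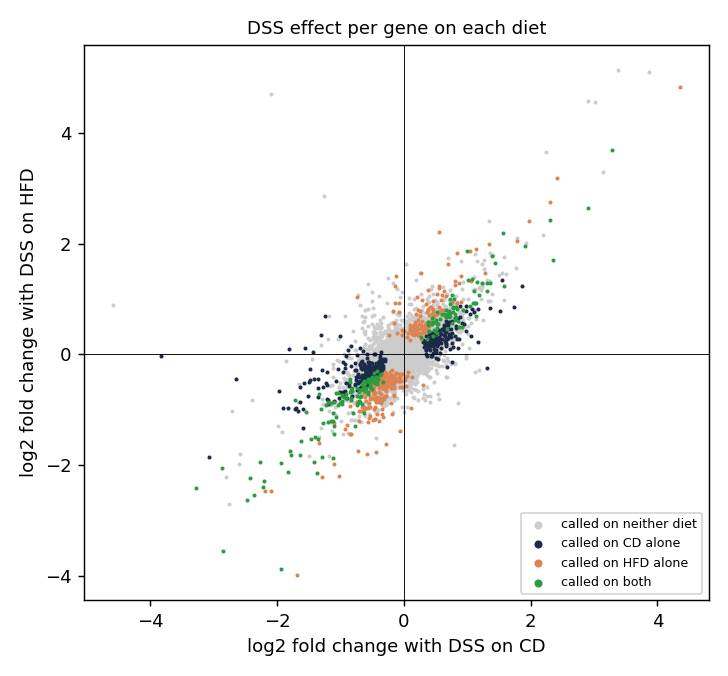
Log2 fold change of each of the 10806 tested genes with DSS on the CD diet (x axis) and on the high-fat diet (y axis), 1 point per gene, coloured by the comparison in which limma called it. The 72 genes called higher and the 116 called lower on both diets lie along the diagonal, and Pearson r is 0.716.

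Without DSS, limma called 1 gene between the diets. Ugt1a9, a UDP-glucuronosyltransferase, fell from 26.1 ± 1.5 FPKM in CD to 6.33 ± 0.671 in HFD (SD, n = 3), a 3.70-fold decrease of FPKM + 1 (log2 fold change −1.89, SE 0.21, limma adjusted p = 0.0197). Ugt1a9 (ENSMUSG00000090175) lies on chromosome 1 from 88070800 to 88218997 (mm10) and shares 59.9% of its exon bases with other genes of the Ugt1a locus, so the value depends on how the shared exons were counted. It was the 1 call of limma, against 726 genes at an unadjusted p under 0.05 (540.3 expected), 1 with voom on recovered fragments and 0 under TPM scaling. The call ended without CD 1, 2 or 3 (adjusted p = 0.0925, 0.131 and 0.0858) and without HFD 1, 2 or 3 (0.134, 0.0630 and 0.134). Groups did not overlap in 13.1% of the tested genes, where chance gives 10%. The count was 66 with libraries weighted, 6 from a fit of these 2 groups alone, 6 with no filter and 2 without the 3 intermediate libraries.

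Lipid synthesis genes stood lower on the high-fat diet without DSS, with no single gene called. All 24 cholesterol synthesis genes had a negative log2 fold change (median −0.50, 5 lower adjusted over the list alone, camera adjusted p = 1.02e-14; adjusted p = 0.552 with an estimated correlation). Per library the groups overlapped, with HFD 3 (0.03) above CD 2 (0.0039). The 21 genes of fatty acid and triglyceride synthesis had a median of −0.45, 7 lower adjusted over the list alone (camera adjusted p = 2.53e-08; adjusted p = 0.552 with an estimated correlation). Scd1 was at −2.01 (SE 0.88), Fasn at −1.04 (SE 0.34) and Srebf1 at 0.05 (SE 0.29), none called. Interferon-stimulated genes had a positive sign in 33 of 34 (median 0.29, none called, none adjusted over the list alone, camera adjusted p = 3.21e-09; adjusted p = 0.600 with an estimated correlation). HFD 1 had a median of 0.33 against −0.06 and −0.11 in HFD 2 and 3 and −0.33 to −0.25 in CD. The 32 fatty acid oxidation and PPARA target genes had a median of 0.17, 2 higher adjusted over the list alone (camera adjusted p = 6.41e-05; adjusted p = 0.656 with an estimated correlation). In this list HFD 1 (−0.04) lay within the range of CD (−0.08 to −0.02), against 0.29 and 0.14 in HFD 2 and 3.

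Other lists with no called gene without DSS were those of xenobiotic metabolism (median −0.34, 2 lower adjusted over the list alone, camera adjusted p = 8.26e-05), gluconeogenesis and glycolysis (−0.15, camera adjusted p = 0.00328) and bile acid synthesis (−0.07, 3 lower adjusted over the list alone, camera adjusted p = 0.0129). Each had an adjusted p = 0.552 with an estimated correlation. Cyp7a1 had −1.84 (SE 0.68) and Cyp8b1 −0.58 (SE 0.17), not called. Lysosomal (−0.07, camera adjusted p = 9.94e-04), fibrosis (−0.21, 2.82e-04), endothelial (−0.21, 0.00284) and glutathione genes (−0.22, 0.00328) were lower as lists with none called, over all genes or adjusted over the list alone (adjusted p = 0.600, 0.600, 0.656 and 0.656 with an estimated correlation). Endothelial and bile acid synthesis list calls ended without HFD 1 (0.318 and 0.112), fibrosis and glutathione list calls without CD 1 (0.143 and 0.0741). Without the 3 intermediate libraries the endothelial and bile acid synthesis calls ended (0.241 and 0.0963), the latter also with libraries weighted (0.212), and at a mean of at least 5 FPKM the fibrosis call (0.132). HFD 1 had a median endothelial deviation of −0.40 against −0.02 and 0.08 in HFD 2 and 3. Medians per library overlapped between CD and HFD in 7 of the 11 called lists, those of bile acid synthesis, cholesterol synthesis, fatty acid oxidation, xenobiotic metabolism, glutathione, fibrosis and endothelial genes. The remaining genes fixed in advance had log2 fold changes of 1.13 (Saa1), 1.27 (Saa2), 0.78 (Lcn2), 0.27 (Hamp), −0.03 (Adgre1), −0.02 (Cd36), −0.46 (Nr0b2) and −0.16 (Abcb11), none called.

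With DSS, limma called 11 genes between the diets. BC049987 (ENSMUSG00000110755), a long intergenic noncoding RNA on chromosome 9 from 44670453 to 44672238 (mm10), was 3.16-fold higher on the high-fat diet, at 7.92 ± 1.27 FPKM in HFD_DSS and 1.82 ± 0.358 in CD_DSS (SD, n = 3; limma adjusted p = 6.76e-04). Mup11, a major urinary protein gene (2.14, SE 0.28), and Nxpe2 (1.59, SE 0.20) were higher as well. Ugt1a9 was lower by a log2 fold change of −1.93 (SE 0.21, limma adjusted p = 0.00782), as without DSS, at 5.31 ± 1.32 against 23.7 ± 8.68 FPKM (SD, n = 3). Cyp2a5 was 7.84-fold lower, at 2.14 ± 1.11 against 28.1 ± 24.1 FPKM (SD, n = 3; limma adjusted p = 0.0303), and Cyp3a11, a steroid and drug oxidase, 4.08-fold lower (limma adjusted p = 0.0371). Ak4 (−0.90), Cd9 (−0.81), the lysosomal activator protein gene Gm2a (−0.80) and Paics (−0.61) were lower, and the eleventh call, named after its values were seen, was the pseudogene Gm45344 (0.93).

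In the DSS-treated livers, 2 of 21 xenobiotic genes were lower on the high-fat diet (Cyp2a5, Cyp3a11), and 9 were lower adjusted over the list alone (median −0.36, camera adjusted p = 3.46e-06; adjusted p = 0.611 with an estimated correlation). Glutathione and NRF2 genes had none of 25 called and 6 lower adjusted over the list alone (median −0.41, camera adjusted p = 3.46e-06; adjusted p = 0.611 with an estimated correlation). CD_DSS 1 stood apart in both lists, with a median per library of 0.40 against −0.17 and −0.05 in CD_DSS 2 and 3 for xenobiotic genes and 0.30 against −0.11 and −0.19 for glutathione genes. Cholesterol synthesis (median 0.40, 0 adjusted over the list alone) and the unfolded protein response (0.37, 0 adjusted over the list alone) were higher as lists with no called gene (camera adjusted p = 3.46e-06 for both; adjusted p = 0.611 with an estimated correlation for both). In the unfolded protein response HFD_DSS 2 (0.02) lay below CD_DSS 2 and 3 (0.14 and 0.21). Of 19 male-high genes Mup11 was higher, and 6 were higher adjusted over the list alone (median 0.44, camera adjusted p = 5.76e-05; adjusted p = 0.611 with an estimated correlation). Fatty acid and triglyceride synthesis genes had a median of −0.41, 2 lower adjusted over the list alone (camera adjusted p = 3.51e-04; adjusted p = 0.611 with an estimated correlation). Scd1 was at −4.31 (SE 0.88, limma adjusted p = 0.0942), and the list call ended without CD_DSS 1 (0.113). HFD_DSS 2 (−0.08) lay above CD_DSS 2 and 3 (−0.38 and −0.30) in this list. The acute phase list (median 0.56, none called, camera adjusted p = 6.63e-04; adjusted p = 0.806 with an estimated correlation) had a median of −0.04 without CD_DSS 1 (adjusted p = 0.806), and its call ended without HFD_DSS 1 (0.0605) and HFD_DSS 3 (0.0656). Endothelial (−0.31, 1 lower adjusted over the list alone) and lysosomal genes (−0.09) were lower as lists (camera adjusted p = 3.51e-04 and 6.17e-04; adjusted p = 0.611 with an estimated correlation for both), and both calls ended without CD_DSS 3 (0.0819 and 0.0966).

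Limma called 4 genes higher and 7 lower between the diets with DSS (36.4% higher), with 1171 at an unadjusted p under 0.05 (540.3 expected). TPM scaling called 6 higher and 5 lower (54.5% higher). Voom on recovered fragments called 12. All 11 had groups that did not overlap, as did 16.5% of the tested genes, where chance gives 10%. The count was 14, 15 and 3 without CD_DSS 1, 2 and 3, 11, 28 and 3 without HFD_DSS 1, 2 and 3, and 79 without the 3 intermediate libraries. It was 147 with libraries weighted, 21 at a mean of at least 5 FPKM, 5 with no filter and 4 from a fit of these 2 groups alone. Medians per library overlapped between CD_DSS and HFD_DSS in 7 of the 13 called lists (lysosome, fatty acid and triglyceride synthesis, oxidative phosphorylation, acute phase, interferon-stimulated, unfolded protein response and endothelial). BC049987 and Ugt1a9 kept the call without any 1 library, and of 10 genes that the naming rule took as called, 7, 8 and 3 kept it without CD_DSS 1, 2 and 3 and 6, 9 and 2 without HFD_DSS 1, 2 and 3. Mup11, Nxpe2, Cd9 and Gm2a lost it without CD_DSS 3 (adjusted p between 0.0655 and 0.0685) and without HFD_DSS 3 (0.105), and Cyp2a5 without CD_DSS 3, HFD_DSS 1 or HFD_DSS 3 (0.0663, 0.109 and 0.151). Cyp3a11 lost it without CD_DSS 1, CD_DSS 2, HFD_DSS 1 or HFD_DSS 3 (0.0673, 0.0719, 0.109 and 0.160). Diet effects without and with DSS, which share no library, correlated across genes with r = 0.386 and rho = 0.295 (r between 0.215 and 0.443 without single libraries and 0.141 without the 3 intermediate libraries).

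**Figure D4:**
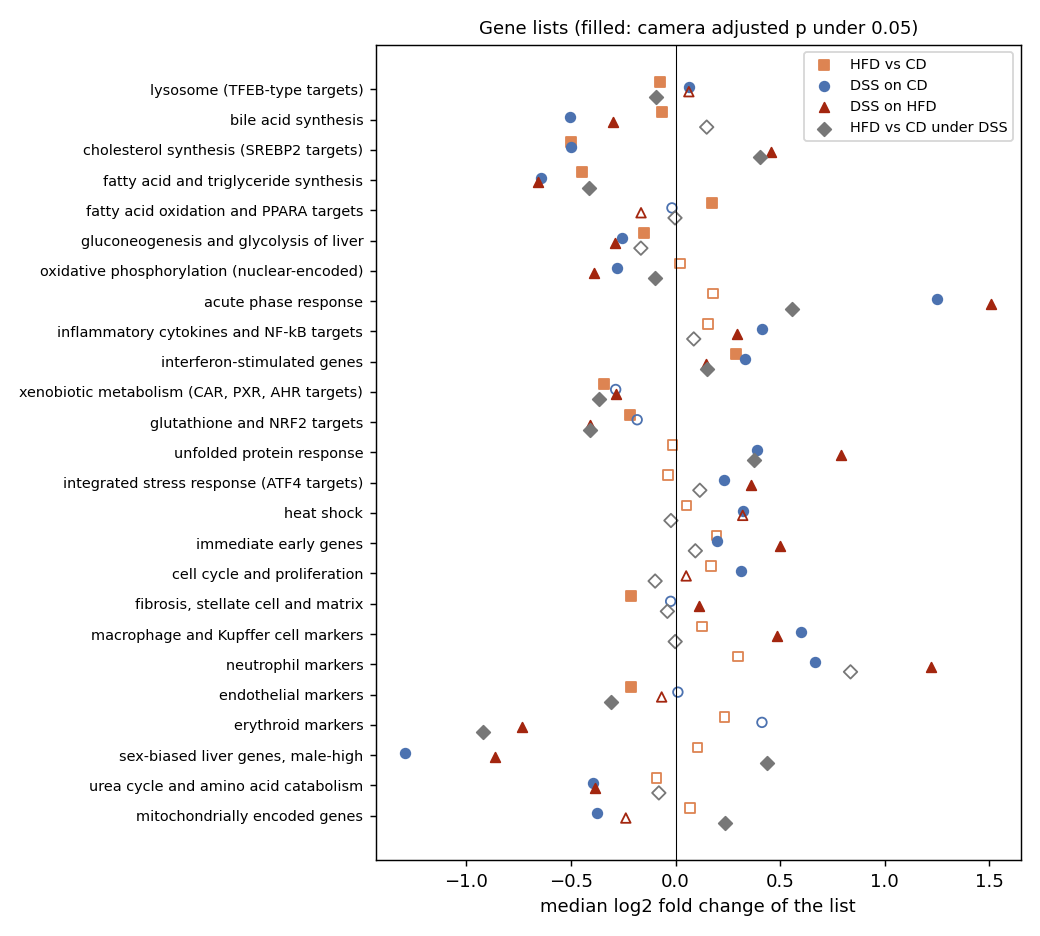
Median log2 fold change of 25 gene lists (one line of points per list) in the 4 comparisons of groups, with filled points where camera with its preset correlation gave an adjusted p under 0.05. The acute phase list lies at 1.25 and 1.51 with DSS on the CD and the high-fat diet, the male-high list at −1.29 and −0.86, and cholesterol synthesis at −0.50 and 0.46.

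The difference between the DSS effects on the 2 diets was called for BC049987, which fell with DSS on the CD diet (−1.55, SE 0.13, limma adjusted p = 0.00137) and not on the high-fat diet (0.11, SE 0.13). The difference was 1.66 (SE 0.19, limma adjusted p = 0.0227). Cyp7a1 fell with DSS on the CD diet and had −0.02 on the high-fat diet, where it was at 8.22 ± 4.47 FPKM without and 10.3 ± 7.68 with DSS (SD, n = 3). The difference of 3.81 (SE 0.96) was not called (limma adjusted p = 0.699). The same held for Cyp8b1 (1.21, SE 0.24, limma adjusted p = 0.491), Serpina4-ps1 (2.20, 0.699), Sqle (1.36, 0.687) and Asns (1.54, 0.699). Scd1, called on the high-fat diet alone, had a difference of −2.30 (SE 1.24, limma adjusted p = 1.00), and Cyp3a11 one of −1.33 (0.958). Genes called on 1 diet were thus not shown to differ between the diets, BC049987 excepted. As a list, all 24 cholesterol synthesis genes had a positive difference (median 0.87, none called, 17 higher adjusted over the list alone, camera adjusted p = 2.15e-24; adjusted p = 0.299 with an estimated correlation). The list medians of the DSS effect were −0.50 on the CD diet and 0.46 on the high-fat diet. The unfolded protein response had a median difference of 0.41 with 0 genes adjusted over the list alone (camera adjusted p = 7.84e-06; adjusted p = 0.915 with an estimated correlation).

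Limma called 1 gene for this difference, with 533 at an unadjusted p under 0.05 (540.3 expected), voom called 1, and 0 were called with no filter or without the 3 intermediate libraries. BC049987 lost its call without CD 1 (0.0683), CD 2 (0.104), HFD 2 (0.0586), HFD 3 (0.0885), CD_DSS 1 (0.102), CD_DSS 3 (0.123), HFD_DSS 1 (0.0979) or HFD_DSS 2 (0.0844), and the count was 2 without CD 3 and without HFD 1.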

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

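The counts over other splits of the libraries and the tests of a swap, a mixture, the scaling and single libraries were chosen only after the result was seen. The tests of gene length and of the assignment of DSS labels to the cholesterol list were written before their results.

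For BC049987 the DSS effect differed between the diets by a log2 value of 1.66 in the test of the difference itself. Of 100 splits of the DSS labels within the diets, the real one among them, 12 called at least as many genes as the real one, which called 1. The highest other count was 881. That split gave the DSS label to HFD 2, HFD 3 and HFD_DSS 2 and left the CD labels as they were, so it adds both DSS effects. Splits that bring DSS effects into the difference do not stand for equal effects on the diets. The share of splits therefore cannot decide on chance, which is not excluded for this count.

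The same test at the preset correlation called 10 gene lists, with median differences of 0.87 for cholesterol synthesis, 0.41 for the unfolded protein response, 0.37 for male-high liver genes, 0.16 for fibrosis and matrix, 0.12 for bile acid synthesis, −0.11 for oxidative phosphorylation, −0.17 for fatty acid oxidation, −0.18 for interferon-stimulated genes, −0.23 for glutathione genes and −1.21 for erythroid markers. None of these lists had a called member, and none was called with an estimated correlation (adjusted p = 0.299 for cholesterol synthesis and 0.915 for the others). Without the 3 intermediate libraries 3 of the 10 were still called, those of cholesterol synthesis, the unfolded protein response and fatty acid oxidation, and the fibrosis median was −0.072. Of the 10, 9 were still called with TPM and with median-of-ratios scaling and 8 with quantile normalization. At a mean of at least 5 FPKM 7 were, as with the replicate number as a block, against 6 with no filter and 4 with libraries weighted. The calls of cholesterol synthesis and the unfolded protein response held without any 1 library, and those of the other 8 did not. Bile acid synthesis lost it without CD 1, CD 3, HFD 1, CD_DSS 2, CD_DSS 3, HFD_DSS 2 or HFD_DSS 3 (camera adjusted p 0.0581 to 0.192), and fatty acid oxidation without CD 1, CD 2, HFD 2, CD_DSS 1, HFD_DSS 1 or HFD_DSS 3 (0.0639 to 0.941). Oxidative phosphorylation lost it without CD 1, HFD 1, HFD 2 or CD_DSS 1 (camera adjusted p 0.102 to 0.271). Interferon-stimulated genes did so without CD 1, CD 3, HFD 1, CD_DSS 2, HFD_DSS 2 or HFD_DSS 3 (0.0639 to 0.874), with a median of −0.0091 without HFD 1. Glutathione genes lost it without CD 2, CD 3, HFD 1, CD_DSS 1, HFD_DSS 1 or HFD_DSS 3 (camera adjusted p 0.0949 to 0.990), with a median of −0.019 without CD_DSS 1. Fibrosis genes did so without CD 1, HFD 1, HFD 2, CD_DSS 1, CD_DSS 2, HFD_DSS 2 or HFD_DSS 3 (0.0581 to 0.654), with a median of 0.018 without CD 1. Erythroid markers lost it without CD 1, CD 3, HFD 1, CD_DSS 3, HFD_DSS 1 or HFD_DSS 2 (camera adjusted p 0.0755 to 0.134), and male-high genes without CD 2, CD 3, HFD 2, CD_DSS 3, HFD_DSS 2 or HFD_DSS 3 (0.0568 to 0.330).

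Of 24 cholesterol synthesis genes, 4 were called lower with DSS on the CD diet and 3 higher on the high-fat diet, with list medians of −0.50 and 0.46 (camera adjusted p = 0.442 and 0.421 with an estimated correlation), and the list call on the high-fat diet ended without the 3 intermediate libraries (0.0933). Scaling of the libraries left the median difference at 0.854 or above, and leaving out single libraries left it at 0.715 or above (without CD_DSS 2), against 0.873 with all 12, which argues against both as the whole cause. In a two-sided permutation over all 400 assignments of the DSS labels within the diets, 8 gave an absolute median as large (p = 0.02). Such assignments stand for no DSS effect on either diet, not for equal effects, so they are not an exact test of the difference. The p-value was also not adjusted for the choice of this list among the 35 tested. A difference between the diets in the response of this pathway is a candidate explanation, as a hypothesis found and tested on the same libraries. Part of the difference lies in the untreated groups, where the list had a median of −0.50 between HFD and CD, and a cause that varies between single mice stays open, since per library HFD_DSS 3 (−0.06) lay below HFD 3 (0.03), and HFD 3 above CD 2 (0.0039).

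HFD 1, CD_DSS 1 and HFD_DSS 2 lay between the other untreated and the other DSS libraries on the first principal component. A swap of HFD 1 and CD_DSS 1 is argued against by a diet score on 100 genes chosen without both, which was 0.584 in HFD 1 and −0.708 in CD_DSS 1, against 0.235 to 0.508 in the other HFD-fed libraries and −0.718 to 0.106 in the other CD-fed libraries. Mixed with untreated liver RNA, CD_DSS 1 would give 1 share in every gene set if its DSS part responded like the other CD_DSS libraries. The share was 0.974 over 31 acute phase genes and 0.269 over 168 genes lower with DSS. The difference was 0.705 (95% bootstrap interval over genes 0.611 to 0.764), which covers the spread of genes alone. This argues against a mixture of that kind, but a DSS part with another response could give unequal shares. Removing the trend on gene length moved no library by more than 0.0900 on that component and left CD_DSS 1 0.640 of the way from the other CD_DSS libraries to CD, against 0.639 before, so it decides nothing (r across genes of the deviations with length −0.303 in HFD 1 and 0.0876 in CD_DSS 1). Gene length bias stays open, as do a single wrong label and a swap with a sample from outside the series. A response to DSS that varied between mice and a mixture with a DSS part of another response stay open too. Apart from gene length bias, these were not tested.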

How the results depend on the processing

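Voom on recovered fragments, the fit without HFD 1, CD_DSS 1 and HFD_DSS 2 and the counts over other splits of the libraries were chosen only after the result was seen.

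Of 139 calls of named genes, all 139 kept direction and threshold with libraries weighted, 138 with a robust prior, 136 with a pseudocount of 0.1, 135 with median-of-ratios scaling, 131 with voom and 134 without the 3 intermediate libraries. With quantile normalization 114 did so, with TPM scaling 101 and with no filter 32, and all 125 tested at a mean of at least 5 FPKM did. Over all settings but single left-out libraries, 1258 values of called genes stayed past the threshold, 257 lost it and none changed sign. With single libraries left out 320 stayed past it, 520 lost it and none changed sign. The fit without the 3 intermediate libraries raised the counts in part by its construction, since these libraries were chosen for lying between the states. A fit of 2 groups alone has fewer libraries for the spread, and the fit with no filter tests more genes. For the other changes below the cause was not tested. Where leaving out a library left a group with 2 samples, the spread was pooled over all groups. Small changes were often missed in simulated data: at a 1.5-fold change, 44% of changed genes were called for DSS on the CD diet. Depth (23.4 to 29.4 M fragments) and the number of libraries per group (3) were not varied, so their part in this was not tested.

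The counts of called genes were 1 (HFD against CD), 519 (DSS on the CD diet), 522 (DSS on the high-fat diet), 11 (diets with DSS) and 1 (difference of DSS effects). In this order they were 6, 220, 122 and 4 from fits of 2 groups alone, 6, 157, 130, 5 and 0 with no filter, and 2, 1924, 2027, 79 and 0 without the 3 intermediate libraries. With libraries weighted the first 4 were 66, 2592, 2820 and 147. A minimum absolute log2 fold change of 1 left 119 and 118 for DSS and 6 between the diets with DSS. At a mean of at least 5 FPKM, 2 genes were called between the diets without and 21 with DSS, and TPM scaling called 0 without DSS. Voom called 1, 534, 533, 12 and 1. The gene lists called were 11, 19, 19, 13 and 10, against 0 in all 5 comparisons with an estimated correlation and 0, 9, 9, 0 and 0 with fry. For the difference of DSS effects they were 6 with no filter and 5 with libraries weighted. The correlation of diet effects was 0.386, and 0.141 without the 3 intermediate libraries, and that of DSS effects lay between 0.655 and 0.757 over the settings other than single left-out libraries.

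With the replicate number as a block, the counts were 3, 290, 278 and 6 in the first 4 comparisons and 1 in the last. The deviations of same-numbered libraries correlated between −0.356 and 0.258, not all over 0.1, and not every library correlated best with its own number, so the numbers were not taken to pair the samples. In the block fit 66 of the 139 named calls and 4 list calls passed the threshold no longer.

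Groups of 3 libraries give 10 splits, too few for a share under 0.05. For HFD against CD 2 of 10 splits gave as many genes (real 1, highest other 1), for DSS on the CD diet 1 (519, highest other 0), for DSS on the high-fat diet 1 (522, highest other 0) and for the diets with DSS 1 (11, highest other 10).

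Values that changed sign were those of genes that were not called and the medians of the fibrosis list and the acute phase list. For the glutathione list the direction of camera turned without CD_DSS 1 while its median stayed negative. With a pseudocount of 0.1, the difference of DSS effects became −0.023 for Fgf21 and −0.071 for Cidec, and with voom −0.22 and −0.022. TPM scaling gave −0.011 for Tfeb between the diets and −0.013 for Cidec in the difference. Quantile normalization gave 0.017 for Nr0b2 with DSS on the CD diet, 0.016 for Sqstm1 between the diets with DSS, and −0.032 for Hamp and −0.011 for Cidec in the difference. With libraries weighted, the values between the diets without DSS were −0.34 (Saa1), −0.071 (Saa2), −0.17 (Lcn2), 0.046 (Adgre1) and 0.056 (Cd36). Those with DSS on the high-fat diet were −0.22 (Nr0b2) and 0.41 (Cyp7a1), Sqstm1 had 0.0020 between the diets with DSS, and the difference was −0.16 for Adgre1 and −0.031 for Fgf21. Without the 3 intermediate libraries, the values between the diets were −0.44 (Saa1), −0.68 (Saa2), −0.64 (Lcn2), 0.041 (Adgre1) and 0.075 (Cd36). Those with DSS on the high-fat diet were −0.23 (Nr0b2), 0.61 (Cyp7a1), 0.34 (Il1b) and −0.26 (Cidec), and those between the diets with DSS 0.039 (Sqstm1) and −0.17 (Cidec). The difference there was −0.072 for the fibrosis list, −0.072 for Nr0b2, −0.34 for Adgre1 and −0.33 for Cidec.

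With single libraries left out, the count ran from 0 to 2 for HFD against CD, from 63 (without CD_DSS 3) to 1271 (without CD_DSS 1) for DSS on the CD diet, and from 9 (without HFD 2) to 879 (without HFD_DSS 2) on the high-fat diet. It ran from 3 (without CD_DSS 3) to 28 (without HFD_DSS 2) between the diets with DSS and from 0 to 2 for the difference, for which 4 (without HFD_DSS 3) to 12 lists (without HFD 3) were called.

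Between the diets without DSS, uncalled values ran from −0.44 to 1.95 (Saa1), −0.0015 to 0.67 (Hamp), −0.68 to 2.25 (Saa2), −0.64 to 1.56 (Lcn2), −0.16 to 0.31 (Srebf1), −0.24 to 0.0010 (Ulk1), −0.11 to 0.089 (Adgre1), −0.075 to 0.075 (Cd36) and −0.041 to 0.047 (Tfeb). With DSS on the CD diet they ran from −0.34 to 0.27 (Nr0b2), −0.0080 to 0.38 (Il1b) and −0.052 to 0.16 (Cidec). On the high-fat diet they ran from −0.22 to 0.18 (Nr0b2), −0.50 to 0.87 (Cyp7a1), −0.34 to 0.28 (Il1b) and −0.29 to 0.33 (Cidec). Between the diets with DSS the ranges were −0.040 to 1.00 (acute phase list), −0.88 to 1.30 (Hamp), −0.059 to 0.030 (Sqstm1), −0.13 to 0.054 (Map1lc3b), −0.36 to 0.25 (Adgre1), −0.29 to 0.0041 (Cd36), −0.043 to 0.0080 (Becn1), −0.14 to 1.05 (Fgf21), −0.050 to 0.57 (Il1b) and −0.17 to 0.46 (Cidec). For the difference they were −0.32 to −0.019 (glutathione list), −0.51 to 2.97 (Saa1), −1.15 to 1.03 (Hamp), −0.49 to 3.48 (Saa2), −0.26 to 0.36 (Nr0b2), −0.033 to 0.15 (Map1lc3b), −0.32 to 0.28 (Adgre1), −0.27 to 0.028 (Cd36), −0.47 to 0.71 (Fgf21), −0.51 to 0.11 (Il1b) and −0.35 to 0.28 (Cidec).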

Other observations

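The comparison of macrophage with endothelial markers was chosen only after the result was seen, and the tests of pericentral and glucocorticoid receptor target genes were written before their results. Called genes of lists that camera did not call, and members of the lists tested here, are named outside the naming rule and were chosen after their values were seen.

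Sox9, a transcription factor of bile duct cells, rose with DSS from 1.76 ± 0.196 to 3.68 ± 0.526 FPKM on the CD diet and from 1.41 ± 0.0523 to 4.07 ± 0.415 on the high-fat diet (SD, n = 3; limma adjusted p = 0.00458 and 8.51e-04). It was the 1 called gene of 4 tested bile duct markers, too few for a list test, and was looked at after its values were seen. Of 4 tested pancreas and gut markers, Cela1 fell on both diets (−1.14 and −1.20), and 1 tested gene of adipose and muscle had 0.07 and 0.05. Among clock genes, Cry1 (−0.75) and Cry2 (−0.52) fell on the high-fat diet, with list medians of −0.19 and −0.09 (camera adjusted p = 0.193 and 0.254). Alas2, of heme synthesis, fell on both diets (−0.90 and −0.72). On the high-fat diet the 6 erythroid markers had a median of −0.73 (camera adjusted p = 0.0177; adjusted p = 0.421 with an estimated correlation), a call that ended without HFD 1 (0.145), HFD_DSS 2 (0.0767) or the 3 intermediate libraries (0.455), with libraries weighted (0.144) and with no filter (0.0596). Between the diets with DSS they had a median of −0.92 (camera adjusted p = 0.0499; adjusted p = 0.611 with an estimated correlation). This call ended without CD_DSS 1 (0.0518), CD_DSS 2 (0.0543), CD_DSS 3 (0.153), HFD_DSS 1 (0.105) or HFD_DSS 2 (0.121), with libraries weighted (0.0798), with quantile normalization (0.0550) and with the replicate number as a block (0.0731). Of 20 fibrosis and matrix genes, Fn1 (0.95) and Dcn (0.71) rose with DSS on the high-fat diet (median 0.11, camera adjusted p = 0.0158; adjusted p = 0.524 with an estimated correlation), a list call that ended without HFD 1 (0.0630), HFD 2 (0.0731), HFD_DSS 2 (0.166) or the 3 intermediate libraries (0.338, median −0.0068). On the CD diet their median was −0.02.

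Among 37 secreted hepatocyte proteins, Angptl8 rose on both diets (1.57 and 1.24), and C3 (1.25) rose and Apoc3 (−0.61) fell on the high-fat diet, with list medians of 0.07 and 0.11 (camera adjusted p = 0.580 and 0.318). Of 17 iron and heme genes, Hamp2 fell and Cp rose on the high-fat diet, with medians of 0.08 and −0.05 (camera adjusted p = 0.419 and 0.514). Heat shock genes had medians of 0.32 on both diets (camera adjusted p = 0.0242 and 0.0953), and cell cycle genes 0.31 and 0.05 (camera adjusted p = 0.0464 and 0.771), with adjusted p = 0.643 with an estimated correlation for both lists on the CD diet. There the heat shock call ended without CD 1 (0.497), CD_DSS 1 (0.0799) or the 3 intermediate libraries (0.110) and with libraries weighted (0.0697). The cell cycle call ended without CD 2, CD 3, CD_DSS 1, CD_DSS 3 or the 3 intermediate libraries (0.128, 0.0514, 0.226, 0.0566 and 0.0717). It also ended with TPM scaling (0.0690), median-of-ratios scaling (0.0558), quantile normalization (0.0774) and libraries weighted (0.0697). DSS left 16 antigen presentation genes at medians of 0.23 and 0.15 (camera adjusted p = 0.0529 and 0.215) and 6 lymphocyte markers at 0.39 and 0.30 with Cd4 lower on the CD diet (−0.58; camera adjusted p of the list 0.584 and 0.215). It left 16 bile acid transport genes at −0.08 and −0.21 (camera adjusted p = 0.125 and 0.0798), 17 lipid droplet genes at −0.06 and −0.18 (0.601 and 0.138) and 36 ribosomal protein genes at 0.02 and 0.00 (0.601 and 0.771). Xenobiotic genes had a median of −0.29 on the CD diet, with Cyp2a5 (−1.94) lower and Cyp3a13 (0.98) higher, and glutathione genes −0.18, with Gstm2 (−1.59) and Pgd (−0.44) lower (camera adjusted p = 0.220 and 0.103). Fatty acid oxidation genes had −0.02 and −0.16, with Cyp4a31 (1.12) higher on the CD diet. The 3 tested female-high liver genes were lower in HFD than in CD adjusted over the list alone (median −0.96), with none called over all genes. Between the diets with DSS, oxidative phosphorylation had −0.10, mitochondrially encoded genes 0.24 and interferon-stimulated genes 0.15 (camera adjusted p = 0.00953, 0.00742 and 0.0357; adjusted p = 0.806, 0.611 and 0.848 with an estimated correlation). The call of oxidative phosphorylation ended without CD_DSS 1 (0.313, median −0.038), HFD_DSS 1 (0.0605) or the 3 intermediate libraries (0.234) and with libraries weighted (0.0605). That of mitochondrially encoded genes ended without CD_DSS 2 (0.0543) or HFD_DSS 1 (0.0740) and with quantile normalization (0.190). That of interferon-stimulated genes ended without CD_DSS 1 (0.175), CD_DSS 3 (0.825, median 0.028), HFD_DSS 1 (0.654, median 0.029) or the 3 intermediate libraries (0.0611), with libraries weighted (0.791) and at a mean of at least 5 FPKM (0.302).

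Macrophage markers had positive medians with DSS on both diets, with 1 and 2 of 16 called (camera adjusted p = 0.417 and 0.421 with an estimated correlation), but CD_DSS 1 (−0.24) lay within the range of CD, and HFD 1 (0.16) above HFD_DSS 2 (0.0026). A lower share of hepatocytes would raise markers of other cell types alike. Macrophage exceeded endothelial markers by a median of 0.587 on the CD diet (95% bootstrap interval over genes 0.454 to 0.735) and 0.551 on the high-fat diet (0.307 to 0.772), which covers the spread of genes alone. Per library the difference was −0.32 in CD_DSS 1 against −0.59 to −0.23 in CD, and 0.56 in HFD 1 against −0.05 in HFD_DSS 2, so the groups overlapped. A lower share of hepatocytes, more macrophages and higher expression per macrophage stay open.

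Glul and Cyp7a1 are expressed around the central vein. Lower beta-catenin target expression there was a candidate cause of their decrease, but Cyp7a1 had 8.22 FPKM in HFD and 10.3 in HFD_DSS. Of 13 other pericentral genes, 11 were tested, and their median log2 fold change was −0.83 (95% bootstrap interval −1.10 to −0.11) on the CD diet and −0.51 (−0.88 to −0.14) on the high-fat diet. Oat (−1.72), Lhpp (−1.21) and Rhbg (−0.83) fell on the CD diet and Rnf43 (−0.88) and Rhbg (−0.79) on the high-fat diet, whereas Axin2 (−0.11 and 0.02), Znrf3 (−0.11 and −0.00072), Tbx3 (0.45 and −0.14) and Nkd1 (−0.25 and −0.20) were called on neither diet. The camera adjusted p was 7.47e-04 and 0.00276 (0.284 for both with an estimated correlation), so the prediction was met in part and the question stays open.

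Zbtb16, a gene that glucocorticoids induce in other tissues, rose with DSS, and glucocorticoid receptor target expression was a candidate explanation. Other targets of the receptor had a median of −0.52 on the CD diet (95% bootstrap interval −0.84 to −0.03) and −0.24 on the high-fat diet (−0.76 to 1.03) over 8 genes, against the direction predicted (camera adjusted p with an estimated correlation 0.284 and 0.761). Fkbp5 rose on both diets (0.99 and 1.87), Tsc22d3 fell on the CD diet (−1.35) and Mfsd2a on the high-fat diet (−1.80), and Cdkn1a (0.08 and 1.03) was not called. Of the 8 genes, 2 had a positive log2 fold change on each diet, so the prediction was not met. The interval below 0 argues against the explanation for these genes on the CD diet, and the high-fat diet stays open. Intervals cover the spread of genes alone, and camera called the list on neither diet.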
